A study of Homo sapiens with 6 samples.

How the data were processed

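RNA was profiled from MCF7-DsRed/luc2 cells recovered by fluorescence-activated sorting from xenografts in 2 sites, the mammary fat pad and the milk ducts, with 3 arrays per site. Per the labels' protocols, total RNA of checked integrity was amplified, labelled with biotin and hybridised to Affymetrix human arrays. The deposited values are log2 expression summaries, 1 per probe set and array, made by RMA, per the submitters' processing notes, which also name Affymetrix Expression Console 1.3.1. RMA in general corrects background, normalizes arrays to a like distribution and summarises the probes of a set. The labels give different RNA inputs in different fields. They also name an array type with fewer probe sets than the 54675 of the table, which match the given annotation, so that annotation was used. More cells were injected into the fat pad than into the ducts, per the labels. Because RMA gives arrays like distributions, a change of most genes in 1 direction would not be seen in these values, and no detection call accompanies them, so that levels near background cannot be told from none. The depth of an array has no equivalent of a read count.

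Groups were taken from the sample labels. The labels number the samples of each group but do not say that each array is a separate mouse. The p-values measure the spread between these samples, part of which may be technical. The labels name no batch. Of the probe sets, 62 controls were left out and 54613 tested. In the annotation 41091 of these have exactly 1 gene symbol, 1801 several and 11721 none, and a gene was named only from a probe set with 1 symbol. Entrez identifiers were looked up in a RefSeq gene table of assembly GRCh38.p14. That table changed 0 symbols and lacked 54 probe sets, and was otherwise used only for the order of neighbouring genes, with no coordinates. No column of per-sample values was left unused.

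The test was limma, which the labels name, here version 3.58.1 in R 4.3.3 (lmFit and eBayes), on all 6 arrays, intraductal minus fat pad. No covariate was used, and the labels mention none. A probe set was called at a Benjamini-Hochberg adjusted p of 0.05 or less and a change of at least 2-fold, the authors' thresholds. The fit had 4 residual degrees of freedom. Gene lists were tested with camera at a preset correlation of 0.01, 2-sided, on 1 probe set per gene (the highest mean over the arrays, 19775 genes), with Benjamini-Hochberg adjustment over the 23 lists. A camera test with an estimated correlation and fry were alternatives. Of the lists, 11 passed camera, 3 upward and 8 downward, 0 passed with an estimated correlation (smallest adjusted p = 0.118; 6 had an unadjusted p under 0.05) and 15 passed fry. In 4 lists (TGF-beta, secretory, progestin and glucocorticoid, adipocyte) the median, mean and test differed in sign. The lists were estrogen-induced genes, luminal differentiation, basal and myoepithelial, TGF-beta response, epithelial-mesenchymal transition, cell cycle, hypoxia, interferon, HLA and antigen presentation, cholesterol synthesis, fatty acid synthesis, secretory differentiation, progestin and glucocorticoid response, immediate-early and dissociation stress, unfolded protein response, p53, oxidative phosphorylation, ribosomal proteins, and markers of fibroblasts, adipocytes, endothelium, leukocytes and erythroid cells. They were written from general knowledge, not from these arrays. Members for which no probe set was chosen were left out, among them AR (luminal), AREG (estrogen-induced), STAT1 and STAT2 (interferon), and HMGCR and LDLR (cholesterol).

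Groups, tests, thresholds, lists, most other settings and the rule for named genes were fixed before the data were examined. The rule took the 8 largest differences per direction among called probe sets with 1 symbol, no overlap of groups and a brighter group above the median of all values, with each gene taken by its qualifying probe set of highest mean over the arrays. It added 15 genes named in advance (ESR1, PGR, GREB1, TFF1, FOXA1, GATA3, KRT8, KRT18, CDH1, KRT5, KRT14, SNAI2, VIM, TGFB1 and MKI67). It further added up to 4 called members per list by size, or the 2 with the smallest p where fewer than 2 were called. This gave 97 genes, of which 79 were called and 0 had a probe set called the opposite way. The other settings fixed then were quantile normalization, median centring, a filter on dim probe sets, other variance models, array weights, other fold thresholds, other rules for probe sets of a gene, leaving out each array, and the replicate number as a block. Scaling to the poly-A spikes, scaling to the hybridisation spikes and the ACTB 3' minus 5' difference as a covariate were added after seeing the data.

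The scripts were tested on simulated arrays of 54613 probe sets with the real means and spreads and independent noise. The changed probe sets, 50 per fold, were drawn only from those with a mean above the median, so the shares passed do not cover dim probe sets. Of probe sets changed 1.5-fold, 28% passed the adjusted p. The shares were 78% for 2-fold, 98% for 3-fold and 100% for 4-fold changes. Both thresholds were passed by 0%, 44%, 98% and 100%, in the same order. Of the calls on adjusted p, 5.59% were unchanged probe sets, and 0 unchanged probe sets passed both thresholds. The figures were drawn with matplotlib 3.10.9.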

Results

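Gene expression was measured in MCF7 cells, an established estrogen receptor-positive human breast cancer line, after growth as xenografts in female SCID Beige mice aged 8 to 12 weeks. The cells carried the red fluorescent protein DsRed and a luciferase. They were injected either into the mammary fat pad (3 arrays) or into the milk ducts (intraductal, 3 arrays), and DsRed-positive cells were sorted from the host tissue before RNA extraction. The comparison asks how expression in the same cell line differs between the ducts and the fat pad, with the luminal phenotype and hormone response named in the study's title. Each array gave log2 RMA values for 54675 probe sets, with array medians between 5.14 and 5.17, and the number of arrays limits the precision. Correlations across probe sets, which are not independent replicates, were 0.993 to 0.995 for the 6 pairs of arrays within a group and 0.965 to 0.971 for the 9 pairs between groups. The first principal component held 77.9% of the variance and separated the groups. All differences are intraductal minus fat pad, on the log2 scale with the standard error of the limma fit, and n = 3 arrays per group throughout.

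Expression differed widely between the sites. Of 54613 probe sets tested, 1573 were higher and 1719 lower in intraductal cells at an adjusted p of 0.05 and a 2-fold change, which is 6.03% of the probe sets. Taken as 1 probe set per gene, 522 genes of 19775 rose and 970 fell (522 and 971 when those probe sets were fitted and adjusted alone). Among 486 genes with at least 2 called probe sets, all called probe sets moved in 1 direction for 484. RMA values are relative to each array's own distribution. With the arrays instead scaled to equal poly-A spike signal, the median of all probe sets moved to -0.69, 423 probe sets were higher and 8916 lower, and the lower share went from 52.2% to 95.5%. Scaling to the hybridisation spikes moved the median to -0.27 and gave 864 higher and 3070 lower, a lower share of 78.0%. Such scaling shifts every gene alike, so every direction stated here is relative to the other genes on the array.

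By the brightest qualifying probe set of each gene, the largest rise was in CPB1, which encodes a carboxypeptidase, from 4.56 ± 0.71 in fat pad cells to 12.77 ± 0.44 in intraductal cells (SD), a difference of 8.21 ± 0.32 or 296-fold (adjusted p = 4.99e-07). KCNE4, a regulatory subunit of potassium channels, rose by 5.81 ± 0.20, NIBAN1 by 5.47 ± 0.25 and the membrane protein gene TM4SF1 by 5.02 ± 0.10 (up to 5.59 on its other probe sets). HOPX rose by 4.61 ± 0.29 on 1 of its 3 probe sets, and the long noncoding RNA DRAIC by 4.20 ± 0.14. The pseudogenes CYP4F30P and CYP4F62P rose by 5.42 ± 0.26 and 4.19 ± 0.13, but signal from near-identical members of the CYP4F family cannot be assigned firmly to 1 copy. On the same basis the largest falls were in 3 genes of small calcium-binding proteins: S100A7 fell by 7.28 ± 0.32, a 155-fold change (adjusted p = 1.1e-06), and S100A2 and S100A8 differed by -6.81 ± 0.14 and -6.31 ± 0.38. CAV1, the main protein of caveolae, had a difference of -5.95 ± 0.19 on its probe set with the higher mean and of -7.45, beyond S100A7, on its other one, ARHGAP36 of -5.91 ± 0.12, the interferon-induced gene IFI27 of -5.81 ± 0.20, the connexin gene GJA1 of -5.71 ± 0.18 and the transcriptional repressor gene SNAI2 of -5.05 ± 0.14. Of the 79 named genes past both thresholds, 29 had a dimmer group under the median of all probe set values (5.15). Without detection calls the size of such a fold is uncertain.

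Relative to the other genes, those of luminal differentiation rose as a list, although their median turned under poly-A spike scaling, and those of basal and myoepithelial cells fell. Both spike scalings lower every intraductal value against the fat pad, so they could only deepen a fall and are no test of it. Of 29 luminal genes measured, 8 rose, 1 fell and 20 did not pass, with a median of 0.68 that turned to -0.019 under poly-A spike scaling (camera adjusted p = 1.65e-06, and adjusted p = 0.118 with an estimated correlation). Under that scaling 2 luminal genes were higher and 4 lower, and under hybridisation spike scaling 5 were higher and 1 lower, with a median of 0.40. With the mean of all probe sets of a gene the luminal median was 0.45. In the basal list TP63, KRT17, KRT6A, KRT6B, LAMA3, LAMC2 and COL17A1 had no chosen probe set with exactly 1 symbol and were left out. Of 25 basal genes measured, 15 fell, 0 rose and 10 did not pass, with a median of -1.58, or -0.87 with the mean of all probe sets of a gene (camera adjusted p = 3.87e-09, and adjusted p = 0.118 with an estimated correlation). For these and the other 21 lists, the counts adjusted over the list alone were the same as those adjusted over all probe sets. ELF3, an epithelial transcription factor gene, rose by 2.78 ± 0.14, AGR3 by 2.27 ± 0.19 and the tight junction gene CLDN4 by 1.47 ± 0.12. ESR1, which encodes the estrogen receptor alpha, rose from 11.00 ± 0.18 to 12.57 ± 0.28 (SD), a difference of 1.57 ± 0.15 or 2.97-fold (adjusted p = 7.6e-05). That call rested on 2 of 9 ESR1 probe sets. The mean over all of them differed by 0.64, and that of CLDN4 by 0.78. Under poly-A spike scaling ESR1 differed by 0.87 and CLDN4 by 0.77, all below 2-fold. The luminal transcription factor genes FOXA1 and GATA3 differed by 0.68 ± 0.11 (adjusted p = 0.00157) and 0.30 ± 0.09 (adjusted p = 0.0403), below 2-fold, and by -0.019 and -0.40 under poly-A spike scaling. KRT8, KRT18 and CDH1, of luminal keratins and E-cadherin, differed by -0.44 ± 0.12, -0.01 ± 0.09 and 0.23 ± 0.12, none past both thresholds. Under poly-A spike scaling KRT8 passed as lower (-1.14) and CDH1 differed by -0.47, and under hybridisation spike scaling CDH1 differed by -0.053. Among basal genes KRT5 fell from 8.96 ± 0.13 to 5.09 ± 0.03 (SD), a 14.7-fold change (adjusted p = 5.59e-08), and ANXA1 fell by 4.79 ± 0.14, beside S100A2, CAV1 and SNAI2. The ANXA1 call rested on 1 of its 2 probe sets, the other differing by -0.42. KRT14 lay under the array median in both groups, at 4.05 ± 0.22 and 3.53 ± 0.37 (SD), and did not pass (adjusted p = 0.0637), but passed as lower under poly-A spike scaling (-1.23). The ACTB 3' minus 5' probe difference, a measure of RNA integrity, was 2.83 ± 0.24 in the fat pad arrays and 3.21 ± 0.13 in the intraductal arrays (SD), with all 3 intraductal values above all 3 fat pad values.

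**Figure D1:**
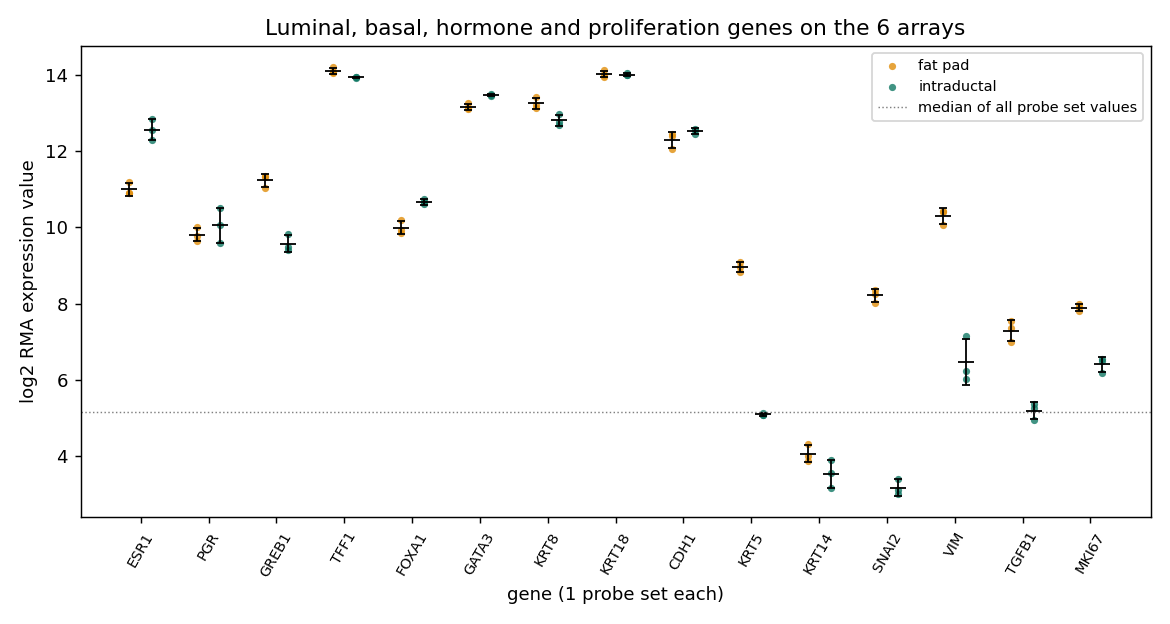
Log2 RMA values (vertical axis) of 15 genes named in advance (horizontal axis, 1 probe set each), with a point per array, the group mean and an SD bar, and n = 3 arrays per group. GREB1, KRT5, SNAI2, VIM, TGFB1 and MKI67 lie lower in intraductal arrays, ESR1 lies higher by 1.57 (0.87 under poly-A spike scaling), and PGR, TFF1, KRT18, CDH1 and KRT14 did not pass the test.

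Genes of epithelial-mesenchymal transition fell for 9 of 21 measured members and rose for 0, while 12 did not pass. The list's median was -0.12 and its mean -1.08 (camera adjusted p = 0.00143, and adjusted p = 0.118 with an estimated correlation). VIM, the gene of the intermediate filament vimentin, went from 10.30 ± 0.20 to 6.46 ± 0.60 (SD), a 14.3-fold fall on 1 of its 2 probe sets (adjusted p = 8.54e-06), the other differing by 0.02. S100A4 fell by 3.08 ± 0.13, and LOXL2, a lysyl oxidase-like gene, fell by 2.81 ± 0.35, although the mean of the 4 LOXL2 probe sets differed by -0.71, below 2-fold. With the camera call kept in each case, the median moved to -0.21 without fat pad replicate 1, -0.20 without intraductal replicate 1, -0.31 without intraductal replicate 3, -0.33 with the ACTB 3' minus 5' covariate, -0.56 with the mean of all probe sets and -2.81 among the brighter probe sets alone, and to -0.82 and -0.41 under poly-A and hybridisation spike scaling. Among the brighter probe sets 5 members were lower. SNAI2 and VIM are members of the basal list as well, so these lists are not independent.

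Genes that estrogen induces moved in both directions and did not pass as a list. Of 34 measured, 2 rose, 10 fell and 22 did not pass, with a median of -0.13 (camera adjusted p = 0.158, and adjusted p = 0.553 with an estimated correlation). Without fat pad replicate 3 the median was -0.078 with 3 higher, and only 1 was higher without fat pad replicate 1, fat pad replicate 2 or intraductal replicate 1. The list passed under fry (adjusted p = 0.00269), which asks only whether its genes move one way. It passed camera under poly-A spike scaling, where its median was -0.83 with 1 gene higher and 16 lower (adjusted p = 0.0133). That scaling lowered every gene alike by 0.70, so in log2 difference the list moved no further relative to the other genes. The list also passed camera with the ACTB 3' minus 5' covariate (median -0.27, adjusted p = 0.0125). GREB1, an early estrogen target, fell by 1.67 ± 0.14 (adjusted p = 3.23e-05) on 1 of 3 probe sets, and the mean of the 3 differed by -0.93. Falls were also found in the serine protease gene PRSS23 (-2.84 ± 0.18), FHL2 (-2.57 ± 0.11) and PDZK1 (-2.28 ± 0.25), while STC2, which is also in the hypoxia list, rose by 2.78 ± 0.18. The progesterone receptor gene PGR had levels of 9.81 ± 0.18 and 10.06 ± 0.46 (SD), a difference of 0.24 ± 0.20 (adjusted p = 0.456) that turned to -0.46 under poly-A and -0.039 under hybridisation spike scaling. TFF1 stood at 14.12 ± 0.08 and 13.95 ± 0.02 (SD), near the top of the range (adjusted p = 0.231). The progestin and glucocorticoid list had 4 genes higher and 4 lower of 20, with a median of 0.026 and a mean of -0.098 (camera adjusted p = 0.719), and 1 higher and 7 lower under poly-A spike scaling. KLF9 rose by 1.85 ± 0.24, while the metallothionein genes MT1X (-2.27 ± 0.12) and MT2A (-2.27 ± 0.11), whose family members are alike in sequence, fell. SGK1 fell by 1.87 ± 0.38. With the ACTB 3' minus 5' difference as a covariate its difference was -2.16, no smaller, but did not pass (adjusted p = 0.0597).

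The gene of the ligand TGFB1 fell from 7.29 ± 0.28 to 5.18 ± 0.22 (SD), a 4.31-fold change (adjusted p = 1.81e-05) on 1 of its 2 probe sets, the other differing by 0.02. The TGF-beta response list divided: 5 of 30 genes rose, 7 fell and 18 did not pass, with a median of 0.22, or 0.091 with the mean of all probe sets of a gene, against a mean of -0.074 (camera adjusted p = 0.494, and adjusted p = 0.756 with an estimated correlation). CCN2, a matricellular growth factor gene, rose by 3.33 ± 0.24 and BAMBI, a TGF-beta pseudoreceptor gene, by 2.39 ± 0.13. IGFBP3 fell by 2.17 ± 0.18 on 1 of its 2 probe sets (-0.85 on the other), beside SNAI2. The median was -0.48 under poly-A spike scaling, with 3 genes higher and 11 lower, and -0.065 under hybridisation spike scaling. Under the latter the list passed camera as higher relative to the other genes (adjusted p = 0.0189). As that scaling shifts every gene alike, it left the log2 differences of the list relative to the other genes unchanged.

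Interferon-response genes fell almost throughout: 29 of 31 measured were lower in intraductal cells, 1 was higher and 1 did not pass, with a median of -2.26 (camera adjusted p = 4.89e-20, and adjusted p = 0.118 with an estimated correlation). IFI27 fell from 12.55 ± 0.06 to 6.74 ± 0.47 (SD), a 56.0-fold change (adjusted p = 2.22e-07). IFIT3 and IFIT1, genes of antiviral proteins, differed by -4.50 ± 0.57 and -4.25 ± 0.46, and IFI44 by -4.21 ± 0.16. The intraductal arrays spread widely for IFIT3 (5.39 ± 1.49, SD) and IFIT1 (6.05 ± 1.17, SD). The gene that rose, IRF1, is a transcription factor of the interferon response and rose by 1.38 (chosen after its value was seen). Under poly-A spike scaling 0 genes of the list were higher and 30 lower. Of 18 genes of HLA and antigen presentation, 10 fell and 8 did not pass, with a median of -1.10 (camera adjusted p = 8.9e-06, and adjusted p = 0.252 with an estimated correlation), or -1.80 under poly-A spike scaling. The peptide transporter gene TAP2 fell by 2.10 ± 0.12, and differences of -2.03 ± 0.15 and -1.94 ± 0.17 were found for the immunoproteasome genes PSMB8 and PSMB9 and of -1.84 ± 0.11 for HLA-B. The mean of the 4 TAP2 probe sets differed by -0.92, and HLA class I genes share sequence, so HLA-B probe sets can read related transcripts. PSMB8, PSMB9 and TAP1 belong to both lists. The ACTB 3' minus 5' difference was higher by 0.39 and the GAPDH one by 0.35 in the intraductal arrays. Leukocyte and macrophage markers had a median of -0.085 and did not shift as a list (camera adjusted p = 0.618).

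Genes of the cell cycle fell in 30 of 35 measured members and rose in 0, with 5 not passing and a median of -1.52, a 2.87-fold difference (camera adjusted p = 4.93e-19, and adjusted p = 0.118 with an estimated correlation). MKI67, the gene of the proliferation marker Ki-67, went from 7.90 ± 0.10 to 6.41 ± 0.20 (SD), lower by 2.81-fold (adjusted p = 2.56e-05), and all 4 of its probe sets were called lower, with differences from -1.69 to -1.37. The mitotic genes CDC20 (-2.54 ± 0.22), KIF20A (-2.50 ± 0.14) and BUB1 (-2.30 ± 0.14) fell, as did the ribonucleotide reductase gene RRM2 (-2.28 ± 0.15). For BUB1 this rested on 1 of 5 probe sets, whose mean differed by -0.68. Beside these, the immediate-early and dissociation stress list rose: 8 of 21 genes were higher, 1 was lower and 12 did not pass, with a median of 0.93 that was 0.23 under poly-A spike scaling, where 4 were higher and 3 lower (camera adjusted p = 1.95e-06, and adjusted p = 0.508 with an estimated correlation). GADD45B rose by 2.21 ± 0.15, FOSB by 2.01 ± 0.18, IER3 by 1.81 ± 0.20 and NR4A1 by 1.71 ± 0.19.

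**Figure D2:**
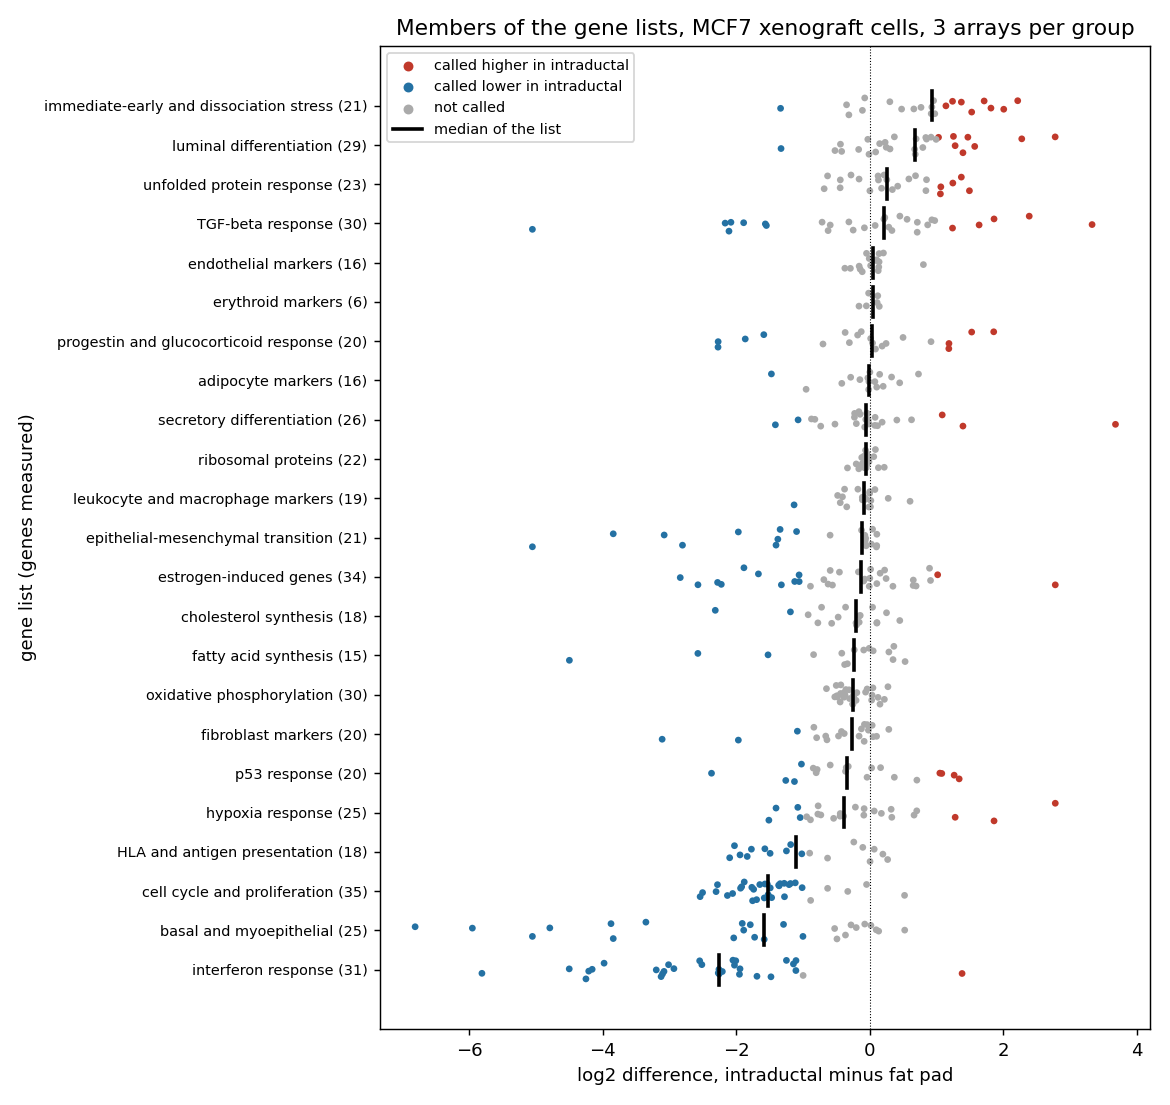
Log2 difference, intraductal minus fat pad (horizontal axis), of each measured member of the 23 gene lists (vertical axis), from 3 arrays per group, with a point per gene coloured by its call and a black bar at the list's median. The medians of the interferon (-2.26), basal (-1.58), cell cycle (-1.52) and HLA (-1.10) lists lie lowest, and those of the immediate-early (0.93) and luminal (0.68, or -0.019 under poly-A spike scaling) lists highest.

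Other stress and metabolic groups had list medians between -0.39 and 0.25. In the unfolded protein response list 5 of 23 genes rose, 0 fell and 18 did not pass, with a median of 0.25 that turned to -0.44 under poly-A and -0.028 under hybridisation spike scaling (camera adjusted p = 0.00162, and adjusted p = 0.261 with an estimated correlation). The counts were 0 higher and 4 lower under poly-A and 2 higher and 0 lower under hybridisation spike scaling. HERPUD1 rose by 1.49 ± 0.11 and DNAJB9 by 1.24 ± 0.12, with 0.79 and 0.54 under poly-A spike scaling. The HERPUD1 call rested on 1 of its 2 probe sets, the other differing by 0.57. Of 18 measured genes of the cholesterol synthesis list, 2 fell, STARD4 (-2.31 ± 0.13) and INSIG1 (-1.19 ± 0.14), neither of them an enzyme of synthesis, and 16 did not pass. The list's median was -0.20 (camera adjusted p = 0.0314, and adjusted p = 0.521 with an estimated correlation), and 8 genes were lower under poly-A and 5 under hybridisation spike scaling. In the fatty acid synthesis list 3 of 15 measured genes fell: FABP5, a fatty acid binding protein gene (-4.50 ± 0.11), ACSL1 (-2.57 ± 0.19) and ME1 (-1.52 ± 0.14). That list had a median of -0.23 (-0.14 without fat pad replicate 3) and did not pass camera (adjusted p = 0.195), but passed fry (adjusted p = 0.000812). It also passed camera under poly-A spike scaling (7 lower, adjusted p = 0.00266), with the ACTB 3' minus 5' covariate (adjusted p = 0.0387) and with the mean of all probe sets (median -0.15, adjusted p = 0.0414). The poly-A scaling shifts every gene alike, so that call shows no further fall relative to the other genes. None of 30 oxidative phosphorylation genes passed both thresholds (21 had an unadjusted p under 0.05), although limma's camera gave a downward shift with a median of -0.25 (adjusted p = 0.0143, and adjusted p = 0.693 with an estimated correlation). Under poly-A spike scaling 14 of the 30 were lower. NDUFA9 and NDUFS3 differed by -0.65 ± 0.14 and -0.49 ± 0.10. The cholesterol call ended without fat pad replicate 1 (median -0.24, adjusted p = 0.0558), without intraductal replicate 2 (median -0.20, adjusted p = 0.0617) and after quantile normalization (median -0.18, adjusted p = 0.0576), and the oxidative phosphorylation call ended without intraductal replicate 2 (median -0.24, adjusted p = 0.0590), with the ACTB 3' minus 5' covariate (median -0.26) and with the mean of all probe sets (median -0.20, adjusted p = 0.109). Neither call held among the brighter probe sets alone, where both medians were unchanged, or under poly-A spike scaling, where they were -0.90 and -0.95. The hypoxia list had 3 genes higher and 4 lower of 25 (median -0.39, or -0.23 with the mean of all probe sets, camera adjusted p = 0.618). It had 2 lower without fat pad replicate 2 (median -0.21), 6 lower without fat pad replicate 3, and 2 higher against 13 and 9 lower under poly-A and hybridisation spike scaling. In it were ANGPTL4 higher by 1.86 ± 0.13 and the prolyl hydroxylase gene P4HA2 lower (-1.51 ± 0.20, or -0.93 over the mean of its probe sets). The p53 list had 4 higher and 4 lower of 20 (median -0.34, or -0.20 without fat pad replicate 3, camera adjusted p = 0.618) and passed fry (adjusted p = 0.0058). It had 0 higher and 11 lower under poly-A spike scaling, 1 and 7 under hybridisation spike scaling, and 2 and 3 without intraductal replicate 2. In it MDM2 rose by 1.34 ± 0.12, with 0.64 under poly-A spike scaling and 0.81 over the mean of its probe sets, and FAS fell by 2.37 ± 0.17. The 5 FAS probe sets ranged from -2.37 to 0.14, with 2 called lower. The secretory list had 3 higher and 2 lower of 26, with a median of -0.053 and a mean of 0.037 (camera adjusted p = 0.840). The count lower was 1 without fat pad replicate 1 or intraductal replicate 1 and 3 without fat pad replicate 2 or intraductal replicate 2. With the ACTB 3' minus 5' covariate 2 were higher and 1 lower, and under poly-A spike scaling 1 and 6. AZGP1, a secreted glycoprotein gene, rose by 3.68 ± 0.28, and LCN2 fell by 1.41 ± 0.18. Of 22 ribosomal protein genes 0 passed both limma thresholds and 2 had an unadjusted p under 0.05, with a median of -0.059 (camera adjusted p = 0.692), and RPS19 and RPS27 differed by -0.33 ± 0.09 and 0.22 ± 0.09.

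Markers of other cell types of the host tissue were mostly dim. Of 20 fibroblast markers 3 fell and 17 did not pass, with a median of -0.27 (camera adjusted p = 0.0199, and adjusted p = 0.175 with an estimated correlation), a call that ended among the brighter probe sets alone (median -0.16, adjusted p = 0.399). The median was -0.15 without fat pad replicate 2 and with the mean of all probe sets, and 10 markers were lower under poly-A spike scaling. COL5A1, of a fibrillar collagen, fell by 3.11 ± 0.22 and COL1A2 fell by 1.97 ± 0.21, though the mean of the 3 COL1A2 probe sets differed by -0.66. Of 16 adipocyte markers 1 fell, CD36 (-1.47 ± 0.15, or -0.64 over the mean of its probe sets), with a list median of -0.0068 (camera adjusted p = 0.735). Without fat pad replicate 2 and under hybridisation spike scaling 2 were lower, and 3 with the ACTB 3' minus 5' covariate and under poly-A spike scaling. CEBPA passed in each of these, at -1.06, -1.24, -1.01 and -1.65. Of 19 leukocyte and macrophage markers 1 fell (6 under poly-A spike scaling), CORO1A (-1.13 ± 0.23), whose difference was -0.96 without fat pad replicate 1, -0.94 without intraductal replicate 1 and -0.71 with the ACTB 3' minus 5' covariate. None of 16 endothelial markers (median 0.050, limma camera adjusted p = 0.618) and none of 6 erythroid markers (median 0.046, limma camera adjusted p = 0.692) passed both thresholds, and 3 and 0 of them had an unadjusted p under 0.05.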

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

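Tests chosen only after the result was seen were those of host leukocyte and stromal RNA and of the scaling of arrays, and the covariate fits were added once the control probe sets had been seen. The control probe sets were left out of the main test and used only for the spike scalings, the covariates and the comparisons given here. Among them the spikes and the 3' minus 5' and 3' minus middle differences of GAPDH and ACTB lay above the fat pad level in all 3 intraductal arrays. The poly-A spikes, bacterial transcripts mixed into the RNA, were higher by 0.70 (9.79 ± 0.17 against 10.49 ± 0.19, SD, n = 3), and the hybridisation spikes by 0.28. The 3' minus 5' difference was higher by 0.35 for GAPDH and 0.39 for ACTB, and the 3' minus middle difference by 0.34 and 0.37. For each of these the 2-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. Other controls were lower: those for STAT1, an interferon-induced gene, differed by -1.63 at the 3' end.

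Only 10 splits of the 6 arrays exist, too few for a share under 0.05. The real split, 1 of 10, gave 1573 higher and 1719 lower probe sets, and the highest of the other splits gave 0. For gene lists the real split, again 1 of 10, gave 11 and the highest other gave 7. Every other split mixes the sites unequally, so part of the site difference stays in its contrast and the rest widens its residual. The other splits therefore show neither a chance level for the probe sets nor false calls by camera.

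The interferon list had a median of -2.26. With the ACTB 3' minus 5' difference as a covariate the median was -2.19 and the mean score -2.35 ± 0.27. The slope of this covariate was estimated within each site, and its values did not overlap between the sites. That fit therefore cannot exclude an effect of lower RNA integrity common to all intraductal arrays. RNA of host leukocytes in the fat pad sort, which the DsRed gate should remove, cannot be told apart: its marker list differed by -0.085, but human probes need not read mouse RNA. Only 6 of 19 markers lay above the array median of 5.15, with LCP1 the brightest at 7.19 and lower (-0.41), and epithelial cells can express such genes. An effect of the site of growth was not tested apart from these.

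Basal genes were lower (-1.58) and luminal genes higher (0.68). With the ACTB covariate the basal median was -1.14 and its mean score -1.72 ± 0.09. For the same reason this fit cannot exclude an integrity effect common to a whole site. RNA of host stromal cells, which the DsRed gate should remove, cannot be told apart, since fibroblast markers differed by -0.27 and 9 of 20 lay above the array median, with COL1A1 the brightest at 7.48 but higher in intraductal cells (0.28). Whether the luminal median is above 0 cannot be told apart from scaling of arrays: with poly-A spikes set equal it was -0.019, a value fixed by the spike difference of 0.70, since every gene shifts alike. Under that scaling camera with the preset correlation still gave the list as higher than the other genes (adjusted p = 1.3e-07). An equal shift leaves log2 differences relative to the other genes unchanged, so this result is no further support. With an estimated correlation, tested only without spike scaling, the list did not pass (camera adjusted p = 0.118). Which scale is right stays open, because spike signal depends on RNA input, stated in different amounts, and the site of growth was not tested apart from it.

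Cell cycle genes had a median of -1.52. With the ACTB covariate the median was -1.65, and with the immediate-early score of each array, a measure of handling stress, it was -1.69 (mean score -1.74 ± 0.18). The fit with the ACTB covariate cannot exclude an effect of RNA integrity common to a whole site, because its slope was estimated within each site. The immediate-early score ranged from -0.51 to -0.22 in fat pad arrays and from 0.25 to 0.68 in intraductal arrays, without overlap. Its slope was estimated within each site, so that fit cannot exclude stress of dissociation and sorting common to a whole site. Slower proliferation in the ducts may be a hypothesis, but the number of cells injected also differed between sites and cannot be told apart from the site.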

How the results depend on the processing

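The spike scalings and the ACTB covariate were chosen after seeing the data. Counts of probe sets stayed within 1.5 times the reported 1573 and 1719 under quantile normalization, median centring, the filter on dim probe sets, trend and robust fitting, array weights and treat, and ranged from 1489 to 1667 higher and from 1642 to 1812 lower without each array in turn. With the replicate number as a block, 1575 were higher and 1720 lower. The deviations of same-numbered arrays correlated by 0.119, 0.051 and 0.0032, and not every array correlated best with its own number, so the numbers were not taken to pair the samples. Poly-A spike scaling gave 423 and 8916, keeping 2140 of the 3292 calls, and hybridisation spike scaling 864 and 3070, keeping 2582. The adjusted p alone gave 6667 and 7409, 1 probe set per gene, fitted alone, 522 and 971, and the set without probe sets whose names end in _x_at or _s_at 1146 and 1075. The last 2 test fewer probe sets, and scaling moves every value of an array. With an estimated correlation 0 lists shifted, including luminal (0.68), basal (-1.58) and epithelial-mesenchymal transition (-0.12). Estrogen-induced genes passed under poly-A scaling (-0.83), the ACTB covariate (-0.27) and fry (-0.13, the same median). The TGF-beta list passed under hybridisation scaling (-0.065, a median against an upward test) and turned under fry (0.22, a median against a downward test). Spike scaling shifts every gene alike, so a call gained under it does not come from a log2 move of the list against the other genes. The cause of these changes was otherwise not tested.

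Of the lists past camera, the luminal median turned under poly-A scaling (-0.019) and the unfolded protein response median under poly-A (-0.44) and hybridisation scaling (-0.028), while camera, which compares with the other genes, stayed upward. Lists not past camera whose test turned were ribosomal proteins (-0.028, quantile normalization), progestin and glucocorticoid (-0.67), ribosomal (-0.76) and adipocyte (-0.71) under poly-A scaling, and hypoxia (-0.67) and p53 (-0.62) under hybridisation scaling. Under the ACTB covariate hypoxia (0.056), progestin (-0.054), adipocyte (-0.13) and erythroid (-0.088) turned. Under fry secretory (-0.053), progestin (0.026, adjusted p = 0.0424) and adipocyte (-0.0068) turned, as did secretory with the mean of all probe sets (-0.053). The secretory test also turned without fat pad replicate 2 (-0.056) and without intraductal replicate 2 (-0.10), and the adipocyte test without fat pad replicate 2 (-0.034). Without each array the secretory median ranged from -0.10 to -0.040, the adipocyte median from -0.034 to 0.055 and the progestin median from -0.038 to 0.022. The leukocyte median was -0.23 among the brighter probe sets, and 13 immediate-early genes were higher with the ACTB covariate. Named genes that turned under poly-A scaling, none past both thresholds, were PGR (-0.46), FOXA1 (-0.019), GATA3 (-0.40), CDH1 (-0.47), RPS27 (-0.48), CD14 (-0.097) and HBB (-0.56), and under hybridisation scaling PGR (-0.039), CDH1 (-0.053), RPS27 (-0.066) and HBB (-0.14). KRT18 was 0.0024 with array weights and between -0.045 and 0.037 without each array. Of 97 named genes, 16 lost their call with the mean of all probe sets of a gene, 10 under poly-A scaling, 5 with the ACTB covariate and 4 under hybridisation scaling. Of the 5, POSTN (-1.16) and SGK1 (-2.16) kept their size. Under poly-A scaling 7 gained a call, all lower: KRT8 (-1.14), KRT14 (-1.23), NDUFS3 (-1.19), NDUFA9 (-1.35), RPS19 (-1.03), CEBPA (-1.65) and ENG (-1.07). CEBPA also gained one under hybridisation scaling (-1.24), with the ACTB covariate (-1.01) and without fat pad replicate 2 (-1.06). The cause was not tested. Signal near background limits the folds of dim genes.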

Other observations

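All hypothesis tests here except that along chromosomes were chosen after the result was seen, and p-values of the 5 lists tested by limma's camera are adjusted over those 5. Genes listed for the cornified envelope of squamous epithelial cells were lower as a list in intraductal cells. Of 21 measured members other than S100A7, SPRR1B and genes of the fixed lists, 7 fell and 0 rose, with a median of -0.36 (adjusted p = 0.00374, and adjusted p = 0.105 with an estimated correlation). The keratin gene KRT16 differed by -2.16, the desmosomal genes PKP1 and DSC2 by -2.07 and -1.43 and the protease inhibitor gene PI3 by -1.12, whereas involucrin (IVL, -0.36) and filaggrin (FLG, 0.11) did not pass. A fall of the cornified envelope program may therefore include S100A7 and SPRR1B, as a hypothesis found on the same arrays.

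The S100 genes are neighbours on chromosome 1. Of 45 measured genes from S100A10 to S100A1, 10 fell and 0 rose, among them S100A9 (-3.99), S100A6 (-1.53) and SPRR1B (-4.43), while S100A16 (0.098), S100A13 (0.38) and S100A1 (0.32) did not pass. Of the 10, 6 had already been seen to fall and prompted the test: S100A7, S100A8, S100A9, S100A2, S100A4 and SPRR1B. Of the 39 other neighbours 4 were lower and 0 higher, against 970 lower of all 19775 genes. Camera on these 39 gave an adjusted p of 0.183. As only 15 of them exceeded the array median in either group, a shared change of the region stays open.

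Other target lists gave no clear shift. Wnt feedback targets, tested because AXIN2 and WNT11 were higher, had 2 genes higher of 15 (TNFRSF19 by 2.55, RNF43 by 1.20) and 3 lower, SOX9 (-2.32), DKK1 (-2.10) and APCDD1 (-2.04), with an adjusted p of 0.502. YAP targets other than CCN1 and CCN2 had 1 higher and 2 lower of 13, with an adjusted p of 0.436. Androgen-induced genes, tested because of AZGP1 and CPB1, had 1 higher and 1 lower of 13, with an adjusted p of 0.183. These tests neither show nor exclude a rise.

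Genes 5 to 20 places apart along a chromosome had log2 differences that correlated weakly across 12819 genes, which are not independent replicates (mean 0.0103, against at most 0.00676 in 1000 shuffles of gene order). Only genes with a mean above the array median were used, and differences beyond 2-fold were clipped to 2-fold. A copy number or clonal difference between the groups may contribute, but clusters of co-regulated genes would give the same. Of 1180 overlapping windows of 50 genes, 11 exceeded the limit set by shuffling. The largest were from LRP6 to BMAL2 on chromosome 12 and from ZNF784 to CENPBD2P on chromosome 19, where the mean clipped difference lay 0.35 above that of all genes used (permutation p = 0.001, the smallest these shuffles can give). Others went down, the largest from GORASP2 to COL5A2 on chromosome 2, which differed by -0.31 from that mean (permutation p = 0.004).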
